A study of Mus musculus with 5 samples.

How the data were processed

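The samples were lung tumours of mice in which adenoviral Cre recombinase had been delivered through the trachea, with Dnmt3a either wild-type or deficient and with Kras named in the genotype of both groups, per the labels. Dnmt3a is one of the enzymes that place new methyl groups on cytosine. The assay was methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq): sonicated, denatured tumour DNA was pulled down with an antibody against 5-methylcytosine, and the recovered fragments were amplified and sequenced on a Genome Analyzer II, per the labels' protocols. The number of reads over a region therefore rises with its methylation, with its CpG content and with its copy number, and no input library was used here to part these. The groups held 2 wild-type and 3 deficient samples, taken from the sample titles. The labels do not say whether the samples of a group came from separate animals. A p-value below that compares the samples thus measures only the spread between them, which may be technical. Fisher's exact test, which counts genes, does not measure this spread, and camera compares the genes of a list with other genes.

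Reads of 72 bases had been aligned to the mouse build mm9 with Bowtie, per the submitters' processing notes; the Bowtie version and settings are not given in the sources used here. For each sample the authors deposited the aligned reads, with a constant score of no information, and raw read counts over RefSeq gene bodies, over the 1 kb upstream of each RefSeq transcript (promoters) and over windows of 1000 bases spaced every 900 bases. All coordinates are mm9. How the deposited counts had been made was worked out by recounting the aligned reads. Each value equalled the number of reads, extended by 400 bases to 472 and with duplicates kept, that overlapped the region, plus 1, in 28005 of 28005 gene bodies of every sample, and likewise in all promoters and windows. The counts carried no scaling for depth. Of 2935465 windows 195418 had 10 or more reads in at least 1 sample, and 195255 of these were listed; the other 163 were not, for a reason not found here, and no listed window had fewer. Of the listed windows 37.0% reached that number through deficient replicate 2 alone, the deepest library, against 0.706% for deficient replicate 1. Of the 28005 transcript regions, 97.3% were matched by RefSeq accession to a gene symbol.

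Aligned reads numbered 7289051 and 4427043 in the wild-type samples and 6029842, 10157729 and 5689265 in the deficient samples. A large part of them lay in 10 bins of 10 kb that each held at least 0.03% of the reads of every sample, called high-copy bins here. Reads outside these bins numbered 2290193, 2771244, 1431354, 4230701 and 2881203 in the same order, and 20.2% to 33.1% of them repeated the position and strand of another read. The 95% Wilson intervals of shares were within 0.0451 percentage points; intervals and floors cover counting error only, since amplified reads are not independent molecules. Each library filled 1 lane of a single flow cell, per the read names in the deposited files, so a lane cannot be told apart from its sample.

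The deposited counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), after trimmed mean of M values (TMM) scaling and filterByExpr for gene bodies and promoters, or a summed count of 25 or more for windows. Adjusted p-values are Benjamini-Hochberg values over all regions of a kind, with a region called at an adjusted p under 0.05. Differences are deficient minus wild-type. CPM values are the deposited counts scaled to TMM library sizes, given as mean ± SD with 2 wild-type and 3 deficient samples throughout. Reads are given without the added 1. A fold against a group without reads is a lower bound with 3 reads over the whole group as its floor, and a ratio against 1 to 3 reads is given with its exact 95% counting interval. Single values per sample were compared with two-sided exact permutation tests, which with 10 ways to split the samples cannot go below p = 0.2. The 22 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way and makes no comparison with other genes; lists with fewer than 5 tested members were left out. The tests were checked on simulated counts with 50 regions changed at each fold. Over 20163 gene body regions 34% of 2-fold and 98% of 4-fold changes were recovered with 10 unchanged regions called, over 574 promoters 66% of 4-fold and 86% of 8-fold with 7 unchanged called, and over 170627 windows 4% of 4-fold and 62% of 16-fold with 1 unchanged called. The simulated counts were drawn independently at a single dispersion for each kind of region. They lacked shifts of whole chromosomes and other structure of the real samples, so these figures may be optimistic. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

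The groups, lists, tests and the rule for named genes were fixed before the data were examined. The rule named, for each kind of gene region, up to 10 genes in each direction with the largest log2 difference among called regions whose groups did not overlap and that had a mean count of 20 or more in a group. Predicted and clone-named genes were left out and 1 gene was kept per overlapping set. Where none passed, the 5 with the lowest p were named as not having passed. It added 4 members of each list past its test, Dnmt3a, and the 5 windows with the lowest p in each direction, 1 per 10 kb. Genes outside this rule are named below as chosen after their values were seen. Alternatives covered the scaling, the filter, duplicates, read starts in place of extended reads, scaling per chromosome, DESeq2 (1.42.0), the replicate number as a block, and each sample left out in turn. A correction for CpG content was planned but was not run, since it needs the sequence of the build.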

Results

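Methylated DNA was profiled in 5 mouse lung tumour samples, 2 with wild-type Dnmt3a and 3 with deficient Dnmt3a. The deposited gene body counts summed to 1464512 and 1812261 in the wild-type samples and to 889510, 2533737 and 1733076 in the deficient samples, with medians of 19, 25, 12, 33 and 24 per region. Promoters were sparse, with sums of 58484, 71847, 46806, 79932 and 65816, and 50.7% to 70.9% of them had no read in a given sample. Window counts summed to 10425426, 4734312, 9167003, 13209549 and 6632361. The 10 high-copy bins took 68.6% and 37.4% of the aligned reads of the wild-type samples and 76.3%, 58.3% and 49.4% of those of the deficient samples. A single one, on chromosome 2 from 98500001 to 98510000, took 55.6% and 30.2% against 62.2%, 46.7% and 39.7%. This share ranged more within each group than between the groups (exact permutation p = 0.6).

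The targeted gene was examined first. Dnmt3a (NM_007872, chromosome 12, 3806979 to 3914443) had 124 and 262 reads over its gene body in the wild-type samples and 53, 239 and 191 in the deficient samples. On the TMM scale this was 116 ± 39.7 CPM against 89.9 ± 24.7, a log2 difference of -0.35 (SE 0.25, edgeR adjusted p = 0.684). Its shorter transcript (NM_153743, start 3891743) differed by -0.67 (SE 0.36, adjusted p = 0.571). The log2 differences became 0.055 and 0.24 without wild-type replicate 2. Across 119 windows over Dnmt3a the median summed count was 3 reads in the wild-type and 4 in the deficient samples, and 11 windows had no read in any deficient sample but at most 4 in the wild-type samples. In 19 windows the opposite held, with no read in either wild-type sample but reads in the deficient samples. The window at 3888001, chosen after its values were seen, had 4 and 7 reads against 1, 0 and 0. These counts neither established nor excluded a deleted part of Dnmt3a at this depth. The labels do not name the exons concerned, so these reads did not check the genotype labels.

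The first comparison asked which gene bodies carried a different amount of immunoprecipitated methylated DNA in Dnmt3a-deficient tumours. Gene bodies of 18 genes, in 25 transcript regions, were lower in the deficient samples, and no gene body was called higher. The lowest relative to the wild-type samples was Il4i1, an L-amino acid oxidase of immune cells, with 35 and 22 reads against 0, 3 and 0, a ratio of 29.8 (95% counting interval 9.70 to 149). Mab21l2, a developmental gene of the eye, fell from 32.2 ± 6.53 to 4.31 ± 4.4 CPM, Scarf2, a scavenger receptor family member, from 51.6 ± 7.91 to 10 ± 2.91, and Jak3, the kinase of common gamma chain cytokine receptors, from 68.2 ± 26.4 to 18.1 ± 5.75. The others included Kremen2, a co-receptor in Wnt signalling, and Kiss1r, the kisspeptin receptor.

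Il4i1 (NM_010215, chromosome 7, 52091657 to 52096179) had a log2 difference of -3.93 (SE 0.64, adjusted p = 0.00296). Mab21l2 (NM_011839, chromosome 3, 86349502 to 86352205) had -3.29 (SE 0.53, adjusted p = 0.00296), Kremen2 (NM_028416, chromosome 17, 23878165 to 23882796) -2.65 (SE 0.50, adjusted p = 0.0149) and Kiss1r (NM_053244, chromosome 10, 79379715 to 79385017) -2.33 (SE 0.45, adjusted p = 0.0189). Scarf2 (NM_153790, chromosome 16, 17797374 to 17808380) fell by 2.29 (SE 0.34, adjusted p = 0.00194), the smallest p of all gene bodies. Fkrp, which modifies dystroglycan, fell by 2.24 (SE 0.47, adjusted p = 0.0323), and Frs3, an adaptor of fibroblast growth factor receptors, by 2.13 (SE 0.39, adjusted p = 0.0122). Jak3 (NM_001190830, chromosome 8, 74200281 to 74212212) fell by 1.96 (SE 0.32, adjusted p = 0.00303). Plppr3 fell by 1.90 (SE 0.37, adjusted p = 0.0193) and Tmem151a by 1.84 (SE 0.40, adjusted p = 0.0462). In each of these 10 genes all 3 deficient samples lay below both wild-type samples, as the rule for naming them required. Of the 10, edgeR lost all but Scarf2 without deficient replicate 2 (adjusted p from 0.127 to 0.648), all but Scarf2 and Mab21l2 without deficient replicate 1 (0.0581 to 0.215), Kremen2, Plppr3 and Tmem151a without deficient replicate 3 (0.0961, 0.219 and 0.233), and Il4i1 and Kiss1r without wild-type replicate 1 (0.0566 and 0.0550). Without wild-type replicate 2 edgeR lost Kremen2 (log2 -2.01, adjusted p = 0.306), Tmem151a (-1.10, 0.481), Fkrp (-1.98, 0.169), Frs3 (-1.83, 0.0853) and this transcript of Jak3 (-1.49, 0.0599), while its transcript NM_010589 was still called (-1.52, 0.0375).

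**Figure D1:**
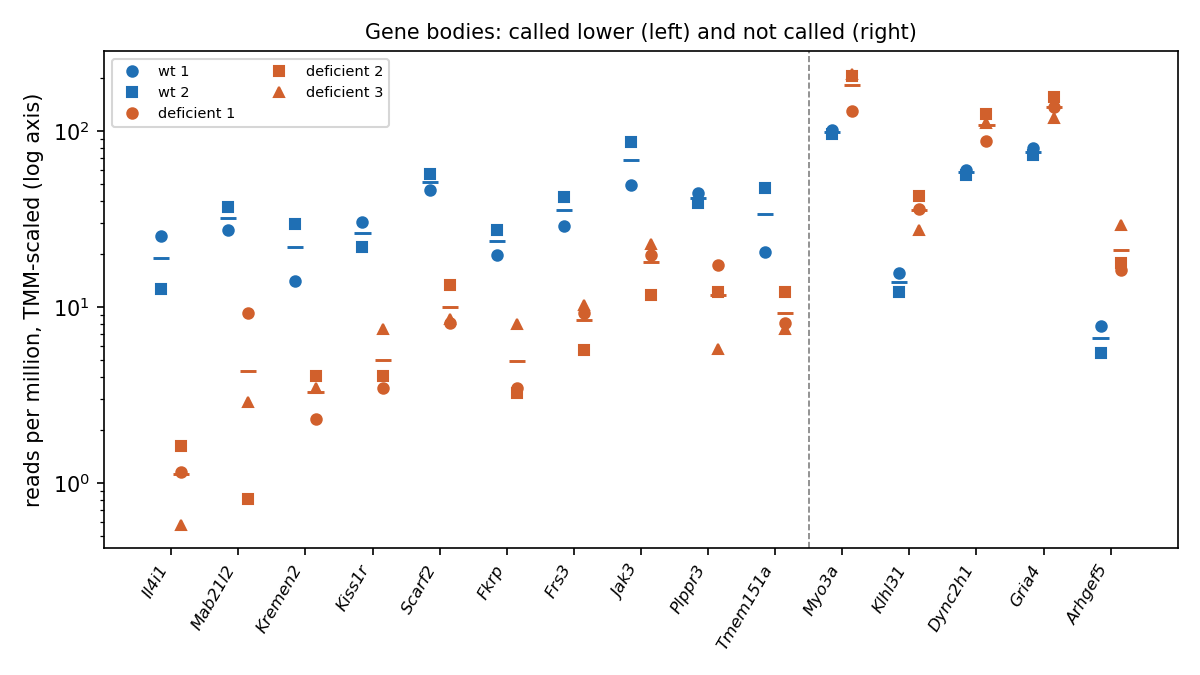
CPM over gene bodies (TMM-scaled, log axis) for the 10 named genes called lower in the deficient samples, left of the dashed line, and the 5 genes with the lowest p among those higher, right of it, which were not called. Each point is 1 sample, short lines are group means, and for all 10 called genes the deficient points lie below both wild-type points, as the rule for naming them required.

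The other 8 called genes were Stap2, Zfp219, Bmp1, Nudt3, Tnxb, Synj2, Gpr180 and Arid1b, named because they complete the set. Their log2 differences ran from -1.74 for Stap2 to -0.98 for Arid1b, a subunit of the SWI/SNF chromatin remodelling complex that fell from 510 ± 66.3 to 258 ± 14.2 CPM (adjusted p = 0.0149). Bmp1, a procollagen protease, fell from 65.5 ± 3.32 to 23.4 ± 8.24 CPM, and Tnxb, an extracellular matrix tenascin, from 131 ± 25.3 to 53.5 ± 9.68. EdgeR called none of these 8 without deficient replicate 1 (adjusted p from 0.0687 to 0.167), 2 (0.327 to 0.699) or 3 (0.110 to 0.233), nor Stap2, Zfp219, Nudt3, Tnxb and Gpr180 without wild-type replicate 2 (0.0556 to 0.281), and Synj2 had -0.57 without wild-type replicate 1 (adjusted p = 0.278). Of the 18 genes, 7 lay on chromosome 17: Kremen2, Frs3, Stap2, Nudt3, Tnxb, Synj2 and Arid1b. Chromosome 17 held 784 of 15675 tested genes, or 5.00% (Fisher's exact test, odds ratio 12.2, p = 1.49e-05, chosen after the calls were seen), and that chromosome's share of the reads outside the high-copy bins was also lower in the deficient samples. The test counts genes as independent, although genes of a chromosome can shift together in the same samples, so its p may overstate the evidence. When each chromosome was scaled on its own, 12 regions of 9 genes were called, 11 of them among the original 25.

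Among gene bodies that were higher, the 5 with the lowest p did not pass the test. Myo3a, an unconventional myosin with a kinase domain, had 99.0 ± 4.0 CPM in the wild-type and 182 ± 45.5 in the deficient samples, a log2 difference of 0.89 (SE 0.23, adjusted p = 0.142). Klhl31 had 1.37 (SE 0.36, adjusted p = 0.147), and Arhgef5, a Rho guanine nucleotide exchange factor, 1.69 (SE 0.46, adjusted p = 0.160). Dync2h1, the heavy chain of the ciliary dynein, had 0.91 (SE 0.24, adjusted p = 0.160) and Gria4, an AMPA receptor subunit, 0.85 (SE 0.23, adjusted p = 0.160). Klhl31, Dync2h1 and Gria4 lay on chromosome 9, whose share of reads was higher in the deficient samples.

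Of 20163 tested regions in 15675 genes, edgeR called 25 lower and 0 higher, with 1168 lower and 781 higher at an unadjusted p under 0.05, and DESeq2 called 13 lower and 0 higher. The groups did not overlap in 2651 regions that were lower and 2576 that were higher, 25.9% of those tested against 20% by chance. The number of calls depended on single samples: 105 lower and 27 higher without wild-type replicate 1, 62 and 10 without wild-type replicate 2, 2 and 0 without deficient replicate 1, 1 and 0 without deficient replicate 2, and 8 and 0 without deficient replicate 3. Scarf2 was called in all 18 alternatives run for it, with adjusted p from 3.89e-05 to 0.0485, and was the single call left without deficient replicate 2, where its adjusted p was 0.0440. Without that sample Il4i1 had a log2 difference of -4.45 and an adjusted p of 0.127, within a range over alternatives of 0.000431 to 0.127, and it was also lost without wild-type replicate 1 (-3.34, adjusted p = 0.0566) and deficient replicate 1 (-3.92, adjusted p = 0.0581). Mab21l2 had -2.58 without deficient replicate 2 (adjusted p = 0.327, within 4.41e-05 to 0.327) and -4.19 without deficient replicate 1.

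Groups of related genes were compared as 22 lists. Vomeronasal receptors, which detect pheromones, rose as a list in the deficient samples, with 62 of 86 tested members above 0 and a median log2 difference of 0.28 (camera adjusted p = 0.00209, but adjusted p = 0.840 with an estimated correlation and 0.406 with fry). Olfactory receptors rose as a list, with 27 of 43 above 0 and a median of 0.35 (adjusted p = 0.0317, but adjusted p = 0.840 with an estimated correlation and 0.406 with fry). Germline genes also rose, with 25 of 33 above 0 and a median of 0.23 (adjusted p = 0.0317, but adjusted p = 0.840 with an estimated correlation and 0.420 with fry). Angiogenesis genes fell as a list, with 33 of 41 below 0 and a median of -0.18 (adjusted p = 0.0282, but adjusted p = 0.828 with an estimated correlation and 0.297 with fry). The sign of these 4 medians was the same under every scaling run, although the olfactory receptors did not pass with each chromosome scaled on its own (adjusted p = 0.0791). Camera with an estimated correlation gave adjusted p from 0.828 to 0.855 for all 22 lists, so it does not tell these 4 lists from the others. Sparsely read regions were in general higher in the deficient samples, with a median log2 ratio of 0.29 in the sparsest of 10 equal groups of autosomal 1 Mb bins and -0.13 in the densest. All values here are relative to the other reads of a library. A rise in sparse regions thus cannot be told apart from a fall in dense ones, and a change across the whole genome would not be seen. The rise of a list is therefore not by itself a gain of methylation. Relative to other autosomal genes in bins of like depth, a comparison chosen after the lists were seen, the median was 0.10 for vomeronasal receptors, 46 of which lay in the 3 sparsest groups, 0.43 for olfactory receptors, 0.23 for germline genes and -0.19 for angiogenesis genes.

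No single member of these 4 lists was called, over all genes or adjusted over the list alone. Among vomeronasal receptors, Vmn2r67 had a log2 difference of 1.83 (SE 0.58), Vmn2r54 1.5 (SE 0.53), Vmn2r56 0.77 (SE 0.34) and the pseudogene Vmn2r-ps54 0.76 (SE 0.31), and near-identical copies in this family leave their counts uncertain. Among olfactory receptors, Olfr288 had 1.42 (SE 0.56), Olfr872 1.22 (SE 0.50), Olfr1033 0.91 (SE 0.47) and Olfr56 0.62 (SE 0.31). Among germline genes, the homeobox genes Rhox9 and Rhox6 of chromosome X had 2.09 (SE 0.72) and 1.66 (SE 0.70), Dmrtb1, a regulator of male germ cells, 1.12 (SE 0.45) and Asz1, of the piRNA pathway, 0.73 (SE 0.31). The largest of these differences rest on few wild-type reads. Rhox9 had 2 and 2 reads against 3, 25 and 13, and Rhox6 4 and 2 against 7, 26 and 6. Vmn2r67 had 3 and 6 against 11, 28 and 19, and Olfr288 4 and 9 against 9, 42 and 12. Without chromosomes X and Y the germline list had an adjusted p of 0.256, and without duplicates 0.119. Among angiogenesis genes, Ccn1, a matricellular protein, had -1.77 (SE 0.60), Notch4, an endothelial Notch receptor, -0.81 (SE 0.28), Col18a1, the source of endostatin, -0.74 (SE 0.22) and Epas1, a hypoxia-inducible factor, -0.69 (SE 0.24), with Notch4 and Epas1 on chromosome 17.

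Leaving out 1 sample changed which lists passed. Angiogenesis genes were lost without deficient replicate 1 (adjusted p = 0.0569) and without wild-type replicate 2 (0.268), and vomeronasal receptors without wild-type replicate 2 (0.124). Germline genes were lost without wild-type replicate 1 (0.268), deficient replicate 2 (0.686) or deficient replicate 3 (0.0712), and olfactory receptors without wild-type replicate 1 (0.105), wild-type replicate 2 (0.0887) or deficient replicate 2 (0.532). Without wild-type replicate 1, developmental transcription factors (adjusted p = 0.00134), the Wnt pathway (0.00348), airway cell markers (0.00711) and the Ras MAPK pathway (0.0438) also passed as lower, but with adjusted p = 0.511, 0.511, 0.561 and 0.511 with an estimated correlation.

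The other 18 lists did not pass, with camera adjusted p from 0.300 to 0.815. The members below 0 numbered 23 of 35 for the Wnt pathway, 20 of 33 for the Ras MAPK pathway, 41 of 56 for clustered protocadherins, 16 of 30 for developmental transcription factors, 12 of 18 for airway markers, 12 of 16 for gut and gastric lineage genes, 9 of 14 for alveolar type 2 markers, 7 of 13 for alveolar type 1 markers, 12 of 18 for endothelial markers and 14 of 23 for fibroblast and smooth muscle markers. Hox cluster genes had 3 of 6 below 0, tumour suppressor genes 19 of 37, cell adhesion genes 27 of 53, keratin and epidermal genes 27 of 53, leukocyte markers 17 of 32, migration and EMT genes 19 of 39, DNA methylation machinery 11 of 23 and imprinted genes 18 of 45. The median and the test differed in sign for tumour suppressor, cell adhesion, keratin and leukocyte genes (median below 0, test higher) and for DNA methylation machinery (median above 0, test lower). Over all genes tested 0 members of these 22 lists were called by edgeR. Adjusted over the list alone 4 members passed edgeR's test: Igf2r, an imprinted receptor (-0.78, SE 0.21, adjusted p = 0.0401), Abca3, the surfactant lipid transporter of alveolar type 2 cells (-0.85, SE 0.27, adjusted p = 0.0466), Cd79a, of the B cell receptor (-2.19, SE 0.63, adjusted p = 0.0378), and Mrc1, the macrophage mannose receptor (0.91, SE 0.28, adjusted p = 0.0378). Over all genes their edgeR adjusted p was 0.160, 0.250, 0.191 and 0.218 in this order. Igf2r and Abca3 lie on chromosome 17, whose 1 Mb bins had a median log2 ratio of -0.41. A shift of that chromosome is not separated from their differences.

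The second comparison asked the same of promoters. No promoter was called in either direction, and the depth left 574 of 28005 promoter regions, of 502 genes, for testing. Mmp16, a membrane-type matrix metalloproteinase (chromosome 4, 17779628 to 17780628), had 15 and 16 reads in its promoter in the wild-type samples and 0, 5 and 3 in the deficient samples (log2 -2.17, SE 0.75, adjusted p = 0.751). Wnt7b, a Wnt ligand (chromosome 15, 85408500 to 85409500), had 12 and 12 reads against 1, 4 and 0 (log2 -2.24, SE 0.90, adjusted p = 0.856). Ak1, an adenylate kinase, had 20 and 14 against 4, 0 and 6, Tmc5 had 8 and 20 against 0, 5 and 3, and Taar1, a trace amine receptor, had 12 and 13 against 1, 5 and 3 (adjusted p = 0.751, 0.856 and 0.885). In the other direction, Ttll6, a tubulin polyglutamylase, had 2 and 4 reads against 10, 15 and 14 (log2 1.94, SE 0.72, adjusted p = 0.780). Arl9 had 0 and 11 against 7, 37 and 22, Macroh2a3 2 and 7 against 7, 30 and 17, Foxr1 6 and 3 against 8, 18 and 17, and Ankrd7 3 and 0 against 12, 16 and 1 (adjusted p = 0.780, 0.840, 0.885 and 0.856).

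Beside the 0 calls by edgeR, 12 promoters were lower and 12 higher at an unadjusted p under 0.05, and DESeq2 called 0, with 8 and 6. With each sample left out in turn, 0 to 1 promoter was called lower and 0 to 2 higher. Of the lists, imprinted genes, germline genes, olfactory receptors and keratin genes had enough promoters to test, and none passed (adjusted p from 0.769 to 0.860). Imprinted genes passed without deficient replicate 3 (adjusted p = 0.0467, but adjusted p = 0.513 with an estimated correlation).

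Across 405 genes tested in both kinds of region, promoter and gene body differences had Pearson's r of 0.321 and Spearman's rho of 0.312, where genes are not independent replicates. Extended reads are shared between a promoter and the gene body next to it, and with reads counted by their start r was 0.0386 over 149 genes. No gene was called in both.

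The third comparison used windows of 1000 bases, which divide the genome more finely. In the deficient samples 37 windows were called lower and 3 higher. Of the lower windows 13 lay at the genes Klf4, Sox2, Myc and Pou5f1, transcription factors that together reprogramme somatic cells to pluripotency, and their reads came almost wholly from wild-type replicate 2. The remaining 24 included windows in Il4i1, Mab21l2, Jak3, Kiss1r, Scarf2, Nudt3 and Stap2, genes whose gene bodies were also called. The higher windows were in Slc15a1, an intestinal peptide transporter, and in an intergenic stretch of chromosome 14.

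The window in Klf4 (chromosome 4, 55542601 to 55543600) had 3 and 230 reads in the wild-type samples and none in the deficient samples, at least 133-fold lower (adjusted p = 2.02e-09). The window in Sox2 (chromosome 3, 34549201 to 34550200) had 5 and 240 reads against 0, 1 and 1, a ratio of 210 (counting interval 57.4 to 1740, adjusted p = 8.96e-09). The window in Myc (chromosome 15, 61819201 to 61820200) had 1 and 201 against 0, 2 and 0, a ratio of 173 (47.2 to 1436, adjusted p = 1.65e-08). At the promoter of Pou5f1 (chromosome 17, 35642701 to 35643700) there were 1 and 86 reads against 0, 3 and 1 (log2 -4.27, SE 0.72, adjusted p = 4.99e-05). In the gene body of Grm7, a metabotropic glutamate receptor (chromosome 6, 110595601 to 110596600), there were 10 and 49 reads against 1, 0 and 0, a ratio of 101 (17.4 to 4052, adjusted p = 0.000112). Without wild-type replicate 2 these 5 windows had too few reads to be tested, edgeR lost those of Sox2, Pou5f1 and Grm7 without deficient replicate 2 (adjusted p = 0.0609, 0.260 and 0.529), and those of Pou5f1 and Grm7 without deficient replicate 3 (0.0714 and 0.0920). Over the whole gene bodies of Klf4, Sox2, Pou5f1 and Myc, wild-type replicate 2 had 304, 250, 183 and 330 reads, 1067 in all, against 20 in wild-type replicate 1 and 6, 15 and 15 in the deficient samples. The windows of these 4 genes thus set wild-type replicate 2 apart from the other 4 samples and not the wild-type from the deficient group.

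**Figure D2:**
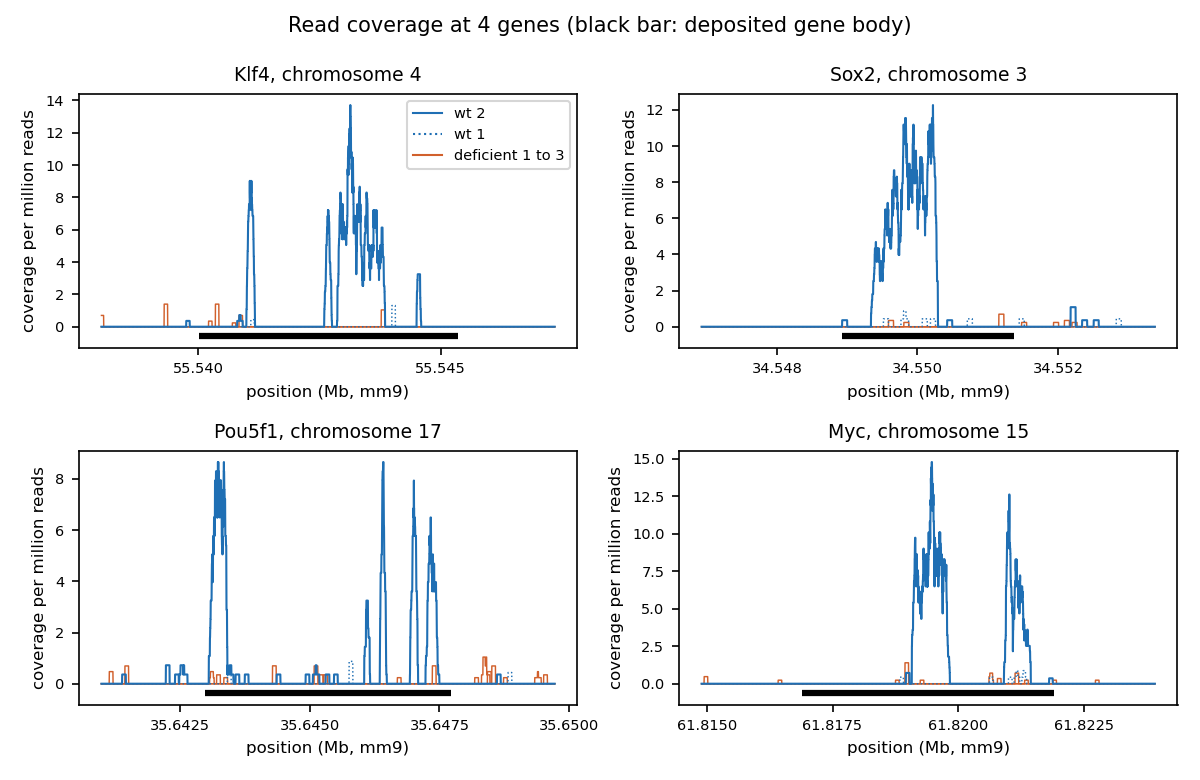
Read coverage, scaled to reads outside the high-copy bins, along Klf4, Sox2, Pou5f1 and Myc (position in Mb, mm9), with the gene body as a black bar. Wild-type replicate 2 (solid blue) rises in separate blocks over each gene, while wild-type replicate 1 (dotted) and the 3 deficient samples (orange) stay near 0.

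In Il4i1 the window at 52094701 on chromosome 7 had 27 and 16 reads against none, at least 24.5-fold lower (adjusted p = 0.000324). In Mab21l2, which lies within Lrba, the window at 86350501 had 31 and 55 reads against 5, 0 and 2 (adjusted p = 0.00257). Windows chosen after their values were seen, as calls in genes not named above, lay in Cyp26c1, a retinoic acid hydroxylase (8 and 47 against 1, 0 and 2, adjusted p = 0.00245), Sema4a, a semaphorin (15 and 46 against 1, 4 and 1, adjusted p = 0.00451), and the protocadherins Pcdh17 (14 and 39 against 1, 5 and 0, adjusted p = 0.0116) and Pcdh8 (23 and 27 against 3, 3 and 0, adjusted p = 0.0280). EdgeR called none of these 6 windows without deficient replicate 2 (adjusted p of 0.393 or more) or 3 (0.0714 to 0.607); without wild-type replicate 2 that of Il4i1 alone (0.00394), and without wild-type replicate 1 that of Pcdh8 was lost (0.164) and that of Il4i1 not tested. Among the higher windows, the one at 52002901 on chromosome 14, 26775 bases from the nearest listed gene, had no read in the wild-type samples and 9, 40 and 23 in the deficient samples, at least 14.0-fold higher (adjusted p = 0.0172), and was called in 1 of the 5 fits with a sample left out. The one in Slc15a1 (chromosome 14, 121866301 to 121867300) had 4 and 2 against 56, 44 and 15 (log2 3.42, SE 0.78, adjusted p = 0.0474), with 2.34 without deficient replicate 1 (adjusted p = 0.520) and no call in any of the 5 fits with a sample left out. The next 3 by p, at 54555301 on chromosome 14 (adjusted p = 0.0719), 6116401 on chromosome 3 (0.155) and 31307401 on chromosome 13 (0.156), did not pass.

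Of 170627 tested windows, the groups did not overlap in 34 of the 40 called. Gene bodies held 32 of the 37 lower windows, 86.5% against 47.1% of tested windows (odds ratio 7.18), promoters 2 and neither 3. The background is unlike the calls, since 37.0% of listed windows were listed through deficient replicate 2 alone and can hardly be called lower. Genic minus other windows differed in median log2 CPM by 0.22 and 0.36 in the wild-type samples and 0, -0.12 and 0 in the deficient samples. Each is a difference between medians of small whole counts, so it moves in steps and a 0 is a tie. In deficient replicate 1 the median over listed windows was 3, so its 0 does not show that genic windows were no higher. The listing may thus set part of this contrast and of the genic difference below. The 13 windows at Klf4, Sox2, Myc and Pou5f1 lie close together at each gene and are not independent, so no interval is given; apart from them gene bodies held 20 of 24, promoters 1 and neither 3, and of the 2 lower windows called without wild-type replicate 2, 50% lay in a gene body or promoter. The median log2 difference was -0.11 in gene bodies, -0.14 in promoters and 0.09 elsewhere, a difference between genic and other windows of -0.20 that was -0.040 without wild-type replicate 2. Scaling per chromosome gave 23 lower and 5 higher windows, and library size alone gave 12 and 0, with a median of all windows of -0.36. Lower calls numbered 44 without wild-type replicate 1, 2 without wild-type replicate 2, 29 without deficient replicate 1, 2 without deficient replicate 2 and 5 without deficient replicate 3, and higher calls 0, 0, 3, 0 and 0.

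Gene bodies as a whole held 44.2% ± 1.46 of the reads outside the high-copy bins in the wild-type and 41.2% ± 0.613 in the deficient samples, with no overlap (exact permutation p = 0.2, the smallest possible). Of all aligned reads they held 21.7% ± 10.3 and 16.7% ± 5.82 (exact permutation p = 0.6), and promoters 0.380% ± 0.212 and 0.273% ± 0.0957 (exact permutation p = 0.6). Wild-type replicate 1, at 14.3% and 0.231%, lay below both deficient means, so the direction of these 2 differences rested on wild-type replicate 2. Over 18072 autosomal genes of at least 2 kb, read density (RPM, reads scaled to those outside the high-copy bins) dipped at the start of genes, to 0.333 RPM per kb in the wild-type and 0.286 in the deficient samples, and rose along the body. In the downstream 10 of 20 equal parts of the body it was 0.721 ± 0.119 and 0.612 ± 0.0174 (exact permutation p = 0.2), with 0.637 in wild-type replicate 1 and 0.805 in wild-type replicate 2. Without the latter the difference was -0.0256. Density was also lower outside genes, at 0.556 against 0.513 from 4 to 5 kb upstream and 0.534 against 0.474 in the 5 kb downstream (exact permutation p = 0.2 each). The downstream part of the body over the upstream 4 to 5 kb was 1.29 against 1.19 (exact permutation p = 0.6).

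**Figure D3:**
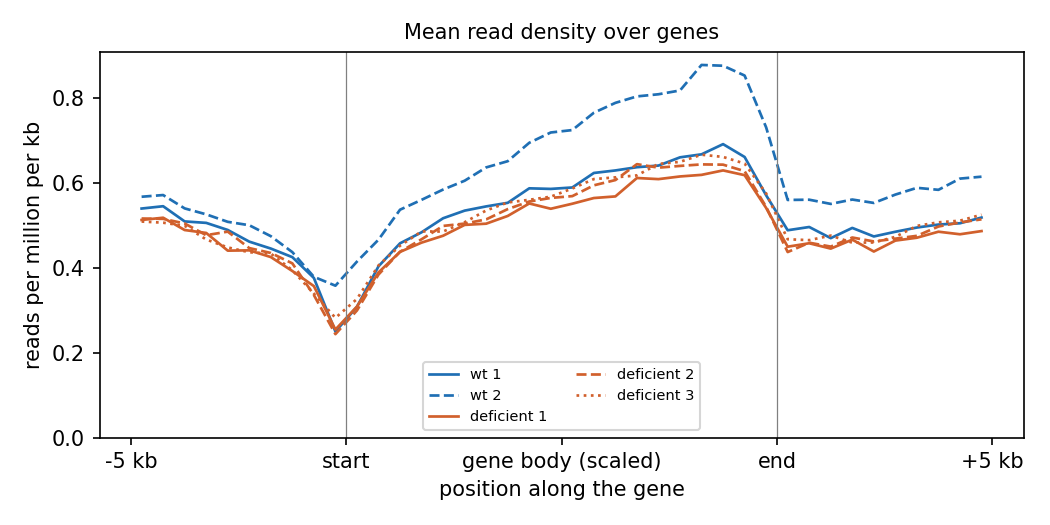
Mean read density (RPM per kb, where RPM counts reads outside the high-copy bins) over 18072 genes, from 5 kb upstream to 5 kb downstream with gene bodies scaled to 1 length. Each line is 1 sample; wild-type replicate 2 lies above the other samples along the body, and wild-type replicate 1 runs close to the 3 deficient samples.

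Chromosomes differed in their share of reads outside the high-copy bins. Chromosome 17 held 5.69% ± 0.321 in the wild-type and 4.09% ± 0.288 in the deficient samples, a ratio of 0.718, with 5.92% and 5.46% against 4.34%, 3.77% and 4.16%. Chromosome 9 went the other way, from 4.01% ± 0.250 to 4.98% ± 0.226, a ratio of 1.24. The groups also did not overlap for chromosomes 3 (6.27% against 5.36%), 10 (5.74% against 5.09%) and 16 (4.11% against 3.60%), lower in the deficient samples, and for chromosomes 6 (6.22% against 7.04%) and 11 (4.53% against 5.06%), higher in them. In each of these 7 the exact permutation p was 0.2, the smallest possible, and the share chance gives for groups without overlap is 20%. The shares of a sample sum to the whole, so a lower share on chromosome 17 raises the others, and the 7 are not independent. Of all aligned reads, where the high-copy bins set the shares, the groups overlapped for every chromosome.

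**Figure D4:**
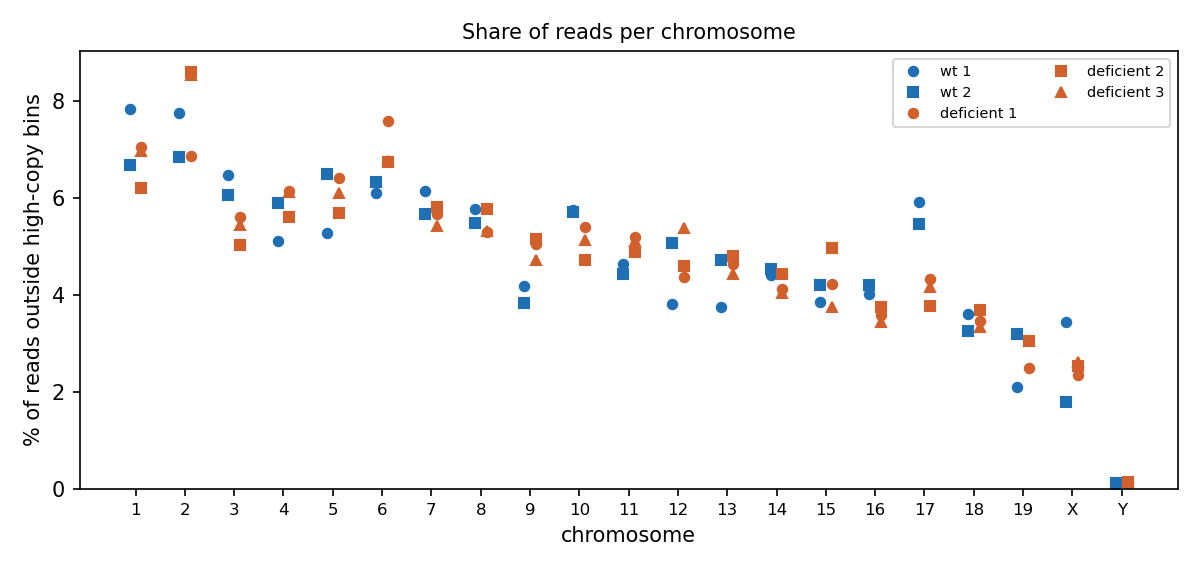
Percent of the reads outside the high-copy bins on each chromosome, with 1 point per sample (wild-type blue, deficient orange). On chromosome 17 both wild-type samples, at 5.92% and 5.46%, lie above all 3 deficient samples, at most 4.34%.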

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

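Scaling by depth outside the high-copy bins, dropping the added 1 or the high-copy bins, counting 1 transcript per gene, matching gene lists on regional depth, testing all windows of the grid and taking shares outside the high-copy bins were chosen after the data were seen; the other alternatives were planned. CpG corrections were not run for want of the build's sequence, nor was a set of promoters apart from their gene bodies, since they adjoin; read starts stood in for it. Among single named genes, named or called windows and the 4 gene lists past the test, 1266 alternatives kept direction and side of the threshold, 319 lost the call (or, for vomeronasal receptors matched on regional depth, shrank to a median of 0.10), 8 gained one and 2 reversed: Dnmt3a without wild-type replicate 2 had log2 differences of 0.055 (NM_007872; -0.63 to 0.055 with a sample left out) and 0.24 (NM_153743; -1.17 to 0.24). The 1266 include regions that were not called at first and stayed uncalled, and fits that gave no adjusted p. Fits in which a region had too few reads to be tested enter none of these numbers. The tally thus does not measure how firm the calls are. With a wild-type sample left out, the lone one was assumed to vary like the deficient samples. Depth limits promoters and windows most: deficient replicate 1 had 1431354 reads outside the high-copy bins.

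Gene bodies called lower, 25, became 45 on autosomes, 52 without duplicates, 12 scaled per chromosome, 13 with DESeq2, 14 by read start, 49 with depth outside the high-copy bins (with a median of all gene bodies of -0.11) and 16 with 1 transcript per gene, where fewer regions were tested; 11 of the 12 and all of the 13, 14 and 16 were among the 25. With a sample left out they ran from 1 to 105 and the higher ones from 0 to 27, with fewer samples. With the replicate number as a block they were 62 lower and 9 higher, and 40 windows lower and 4 higher. The labels do not say that a number marks a litter or batch and only 2 numbers are shared (correlations of deviations 0.150 and 0.0545), so this is no pairing. Promoters ran from 0 to 1 lower and 0 to 2 higher with a sample left out; with depth outside the high-copy bins their median was -0.18 and 0 were called.

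Windows called lower, 37, and higher, 3, became 12 and 0 by library size, 24 lower at a summed count of 50 or more, 19 lower without duplicates, 23 and 5 scaled per chromosome, 20 and 1 without the added 1, and 11 and 1 on all windows of the grid; left-out samples gave 2 to 44 lower and 0 to 3 higher. The percent of lower windows in a gene body or promoter, 91.9, was 100 without duplicates, by library size and without the added 1, and 50 to 100 with a sample left out; the genic difference ran from -0.30 to -0.040. Gene lists past camera, 1 lower and 3 higher, were 0 and 0 with an estimated correlation or fry, and 0 to 5 lower and 1 to 3 higher with a sample left out, while promoter lists numbered 0 to 1.

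Chromosomes whose groups did not overlap, 0 of all aligned reads, were 7 without duplicates, 7 outside the high-copy bins and 7 with both, and 0 to 21 with a sample left out. The chromosome 17 difference outside the high-copy bins, -1.60 percentage points, was -1.07 of all aligned reads and ran from -1.83 to -1.38. Left-out samples gave -12.2 to 2.39 points for gene bodies, -0.257 to 0.0424 for promoters, -41.3 to -0.873 RPM for Dnmt3a and -0.193 to -0.0256 RPM per kb for the downstream part of gene bodies. The correlation of promoter and gene body differences was 0.210 with no filter, 0.444 without duplicates, 0.227 scaled per chromosome, 0.0386 by read start, which shares no reads, and 0.321 to 0.419 with a sample left out. Elsewhere the cause was not tested.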

Other observations

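The tests of explanations and the splits of the samples in this part were chosen after the results they examine had been seen; the window calls and the fits without a sample were planned. Further called windows, lower in the deficient samples and named after their values were seen, lay in genes of varied function. Vstm2b had 16 and 14 reads in the wild-type samples and none in the deficient samples, at least 17.1-fold lower (edgeR adjusted p = 0.0147). Rnf39, in the region of the major histocompatibility complex on chromosome 17, had 14 and 28 against 0, 3 and 0 (adjusted p = 0.0105), and Arhgef40, a Rho guanine nucleotide exchange factor, 16 and 26 against 0, 2 and 1 (0.0115). Stx11, a syntaxin of cytotoxic lymphocytes, had 21 and 22 against 2, 2 and 0 (0.0249), St6galnac3, a sialyltransferase, 25 and 17 against 2, 2 and 0 (0.0264), and Mzf1, a zinc finger factor, 14 and 23 against 1, 0 and 2 (0.0438). A window of the promoter of Mmp23, a matrix metalloproteinase, had 15 and 43 against 1, 2 and 5 (0.0295). Near Fcgr3, an antibody receptor, a window had 3 and 42 against 0, 4 and 1 (0.0287), and near Abca17 one had 40 and 5 against 3, 3 and 0 (0.0379). EdgeR called none of these 9 windows without deficient replicate 2 (adjusted p of 0.481 or more) or 3 (0.191 or more), and without wild-type replicate 2 that near Abca17 alone (0.0135). Without deficient replicate 1 edgeR lost those of Arhgef40, Fcgr3, Mmp23 and Mzf1 (adjusted p from 0.0531 to 0.133), and without wild-type replicate 1 those of Stx11, St6galnac3 and Mzf1 (0.118 to 0.432), with those of Vstm2b and Abca17 not tested.

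The sex chromosomes set wild-type replicate 1 apart. Chromosome Y held 0.00904% of its reads outside the high-copy bins (207 reads, 95% Wilson interval 0.00789 to 0.0104), against 0.124% in wild-type replicate 2 and 0.123%, 0.131% and 0.135% in the deficient samples. Chromosome X held 3.43% in wild-type replicate 1, 1.79% in wild-type replicate 2 and 2.34%, 2.54% and 2.61% in the deficient samples. The labels used here do not give sex. Wild-type replicate 1 alone had almost no Y reads and had the highest share of X, so the groups may be unbalanced in sex. The wild-type samples thus differed from each other on X by more than either did from any deficient sample, and the Rhox genes among the germline genes lie on X.

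Klf4, Sox2, Pou5f1 and Myc together had 385 RPM, scaled to reads outside the high-copy bins, in wild-type replicate 2, 71.0-fold the mean of the other 4 samples. Higher methylation of these genes in the wild-type group is argued against by wild-type replicate 1, at 2.27% of that level, and amplified genomic loci by the flanks within 50 kb, whose reads were 1.13 times those of the other samples. Amplification duplicates alone are argued against by 63.9% of the reads lying at distinct positions. A candidate explanation is DNA carrying the coding sequences without introns, such as a reprogramming vector, in this library alone, which would end coverage sharply at exon edges; coverage fell over a median of 25.5 bases at 14 block edges, at most 56.0, and a median as sharp came in 1.94% of 10000 random sets of 4 other windows but in 3.63%, 7.91% and 5.09% of sets matched on depth from 10, 20 and 40 windows a gene, with a longest edge as short in 0.57% to 1.23% of these. Coverage of 5 or more in wild-type replicate 2 lay in 4 blocks in Klf4, 1 in Sox2, 5 in Pou5f1 and 2 in Myc. Of these gene bodies 71.2%, 55.3%, 64.1% and 71.4% were uncovered. The candidate explanation stays open beside methylated blocks of ordinary DNA, since the share for the median crosses 5% with the number of windows drawn from. No exon coordinates were used here to set against these blocks, and no biological explanation beyond the group was tested.

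On chromosome 17, lower in all 3 deficient samples, a shift along the whole chromosome is consistent with 98.9% of its 1 Mb bins lying below 0 after matching on depth to the other autosomes, but this share is not particular to it, being 99.4% on chromosome 3, 99.0% on 16, 98.4% on 10 and 94.8% on 1, against 0.826% on 9. A trend of the samples on regional depth is argued against by the matched median log2 ratio of -0.42, beside -0.30 on chromosome 3. Such a shift may come from copy number, or from methylation or recovery that differs along the chromosome, and no input library was used here to separate them. Lower methylation along chromosome 17 in the deficient group stays open, since the exact permutation p of 0.2 is the smallest that 2 against 3 samples can give.

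All 25 called gene body regions were lower in the deficient samples. Flanks here were 100 kb on each side, beyond a gap of 5 kb. For the 7 called genes of chromosome 17, the gene body minus its flanks had a median log2 ratio of -0.55 (median SE 0.32). This leaves a shift of the surrounding region open for them as a set and for Tnxb, Arid1b, Synj2 and Nudt3 singly. Kremen2, Frs3 and Stap2 were over 2 SE from their flanks. For the 11 on other chromosomes the median was -1.55 (median SE 0.48). It argues against such a shift as the whole cause in 9 of them and leaves it open for Gpr180 and Bmp1, although all had been picked for extreme values. Gene bodies were on the TMM scale with duplicates kept, flanks on distinct positions scaled to depth outside the high-copy bins. With that depth as the scale the median of all gene bodies was -0.11 against -0.0097, so values near 2 SE decide nothing. Without wild-type replicate 2 the 25 regions, which repeat transcripts of some genes, had a median log2 difference of -1.61 (median SE 0.38). Wild-type replicate 1 thus also lay above the deficient samples. These regions had been called with that sample in the comparison, so this was partly fixed in advance. It cannot tell how far wild-type replicate 2 set the calls. The difference moved by over 1.5 times in Kremen2 and Tmem151a alone. With 2 against 3 samples the 10 splits are too few for a share under 0.05: 2 of them gave as many called regions, the real one with 25 and the highest other, wild-type replicate 1 with deficient replicate 1, with 37. That pair also gave 764 lower and 44 higher windows against 37 and 3 for the real split, which points to a structure of the samples, and it had the highest shares of reads in the high-copy bins, so a technical source and lower methylation without Dnmt3a both remain open hypotheses.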
